A study of Glycine max with 63 samples.

How the data were processed

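The series holds 63 soybean RNA-seq libraries, each with 1 table of 55,900 rows. Per the labels, 27 libraries came from seeds of field plots and 36 from peeled embryos of greenhouse plants, in 21 groups of 3. A field library pooled RNA from 4 genotyped seeds of a plot, and a greenhouse library came from 1 embryo of 1 plant, per the labels' protocols. The 3 replicates of a group were therefore separate plots or plants. The main models treated all libraries as independent, and repeated sampling of a plot over stages was not tested.

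The authors deposited estimated counts of reads per gene, without normalization, per the file headers, after processing for which the submitters name kallisto among their tools. The submitters' processing notes name FastQC 0.11.5, kallisto 0.43.1, sleuth 0.30.0 and R 3.6.3 without giving their roles or order. The genome build, the annotation and the step from transcripts to genes are not given in the sources used here. The counting could divide reads between near-identical gene copies, so values of single genes may include reads of a copy. Between 55.4% and 87.1% of the values in a table were whole numbers, and all values were rounded to whole numbers before testing. Each table listed 55,897 soybean genes, the 2 transgenes AtWRI1 and AtDGAT, and 1 row without a gene name. That row held at most 4 counts, in 1 library, and was left out.

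Total counts ran from 1.17 to 36.2 M in the field libraries and from 3.02 to 23.6 M in the greenhouse libraries. The field totals fell into 17 libraries of 24.2 to 36.2 M and 10 libraries of 1.17 to 4.52 M. In the greenhouse, 31 libraries held 16.0 to 23.6 M and 5 held 3.02 to 7.65 M. A count of 0 allows up to 3 counts, which is 0.0828 to 2.56 counts per 1,000,000 (CPM) in the field libraries and 0.127 to 0.995 CPM in the greenhouse libraries. Intervals and limits of this kind cover counting error only.

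The gene identifiers of the tables matched 0 of the 59,048 genes in the reference table used for names, so genes appear under the identifiers of the tables. For the same reason the 24 gene lists fixed in advance, such as fatty acid synthesis, triacylglycerol assembly and storage proteins, could not be tied to genes, and their tests were not run.

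Groups were taken from the labels alone. Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM, and group means were compared by the 2-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested at 0.05. All adjusted p-values of gene comparisons are from this test unless another tool is named. One model held the 9 field groups (27 libraries, 38,914 genes) and another the 12 greenhouse groups (36 libraries, 34,548 genes). Genotype effects were averaged over the 3 field stages or the 4 greenhouse times, and were also tested at each stage or time. A difference of the effects at R6 and R5 was tested in the same field model. The biological coefficient of variation was 0.284 in the field and 0.168 in the greenhouse. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Levels are given as CPM of all counts for the transgenes, for GLYMA_15G228600 and for greenhouse libraries, and as TMM-normalized CPM where so named, as mean ± SD of 3 libraries unless another number is given. Plots used matplotlib 3.10.9; other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

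The rule for named genes was fixed before the data were examined, as were the main tests and the first set of alternatives. It took the largest changes in each direction for each averaged genotype comparison, among genes past the threshold with a mean of at least 5 CPM in the higher genotype and 1 direction at every stage or time. Since the identifiers carry no gene names, the 2 highest and 2 lowest of these are printed, with both transgenes. The parts of the rule that needed gene names could not be applied. GLYMA_01G081900, GLYMA_15G228700, GLYMA_13G021200 and a stretch of GLYMA_13G identifiers were chosen after their values were seen.

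The test was run on simulated counts with 200 changed genes among those of the real libraries. For the field WD-1 comparison over stages (38,043 genes) it recovered 59% of 2-fold and 79% of 4-fold changes with 5 false calls. For WD-1 at R6 alone it recovered 8% and 52%. For the comparison of libraries labelled WD-1 and WT in the greenhouse (33,517 genes) the shares were 82% and 97% over times, with 15 false calls, and 60% and 95% at 27 days after pollination, with 11 false calls. Simulated comparisons without changed genes gave 0 calls. The simulated libraries varied independently around the mean of each labelled stage or time. Their false calls therefore leave out any structure shared between real libraries. Classes of genes that rise or fall between R5 and R6 by over 2-fold past the threshold were taken from 2 WT libraries per stage, and the lines were compared with the remaining WT library of each stage, for each replicate number in turn. The classes were tested with camera of limma 3.58.1, at its preset and at an estimated correlation between genes.

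Alternatives fixed in advance were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a model of the compared libraries alone, the replicate number as a block, and leaving out each library in turn. Alternatives added after seeing the data used only libraries over 10 M counts, depth class as a covariate, and the counts without 16 genes that followed the most abundant gene. Others left out 13 greenhouse libraries whose transgene counts went against their labels, 2 unusual field libraries, or a stretch of GLYMA_13G genes. In the field, libraries over 10 M counts were only replicate 3 of WT and replicate 2 of WD-1 at R6, and only replicate 1 of W-1 at R5/6. Counts from libraries over 10 M that rest on these groups are given only where marked as such, and are not read as effects of depth. Settings for normalized values did not apply to counts. In each of 63 pairs of replicates the counts differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.78 over genes with at least 20 counts in the pair, so no library was counted as a repeat of another.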

Results

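RNA sequencing followed soybean seeds and embryos that carried Arabidopsis genes for seed oil. AtWRI1 is a transcription factor of fatty acid synthesis, and the AtDGAT row of the tables is the transgene for DGAT1, the enzyme of the last step of triacylglycerol assembly. The parent cultivar Thorne (WT) was compared with the lines W-1 and WD-1 in the field, at the seed stages R5, R5/6 and R6. In the greenhouse, embryos of WT, WD-1 and WD-2 were taken at 24, 27, 30 and 33 days after pollination (DAP). Each of the 9 field groups and 12 greenhouse groups had 3 libraries. Field libraries held 1.17 to 36.2 M counts (1 M is 1,000,000), with at least 1 library under 5 M in 7 of the 9 groups, and greenhouse libraries held 3.02 to 23.6 M.

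In field seeds the transgenes were read in the lines and rose during seed filling. AtWRI1 in W-1 went from 4.42 ± 2.30 CPM at R5 to 126 ± 22.4 at R5/6 and 138 ± 8.55 at R6. In WD-1 it went from 38.5 ± 45.9 to 170 ± 86.5 and 208 ± 36.0 CPM. AtDGAT was read in WD-1 alone, at 4.68 ± 6.99, 13.2 ± 4.99 and 26.5 ± 6.30 CPM, and had 0 counts in W-1 and WT. The 9 WT libraries held 0 AtWRI1 counts apart from 1 R6 library, with 0.398 CPM. Between R5 and R6, AtWRI1 rose 82.0-fold in W-1 (log2 fold change 6.36, SE 0.82, adjusted p = 3.07e-06) and 9.10-fold in WD-1 (3.19, SE 0.68, adjusted p = 0.000916). AtDGAT rose 9.06-fold in WD-1 (3.18, SE 0.88, adjusted p = 0.012). These folds are on the TMM scale and larger than the ratios of the CPM above, since TMM factors of the lines were 1.13 to 1.55 at R5 and 0.578 to 0.920 at R6. As TMM-normalized CPM, AtWRI1 went from 2.99 ± 1.501 to 223 ± 38.3 in W-1 and from 28.5 ± 31.9 to 262 ± 69.1 in WD-1, and AtDGAT from 3.38 ± 4.90 to 33.2 ± 10.0. The folds of WD-1 depend on R5 replicate 2, with 90.8 CPM of AtWRI1 and 12.7 of AtDGAT. Replicate 1 held 4.80 and 0.2 CPM and replicate 3 held 19.9 and 1.11. The AtWRI1 levels of WD-1 and W-1 did not differ past the threshold over stages (log2 fold change 1.25, SE 0.38, adjusted p = 0.177) or at R5, where WD-1 libraries ranged from 4.80 to 90.8 CPM (3.41, SE 0.74, adjusted p = 0.0873).

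**Figure D1:**
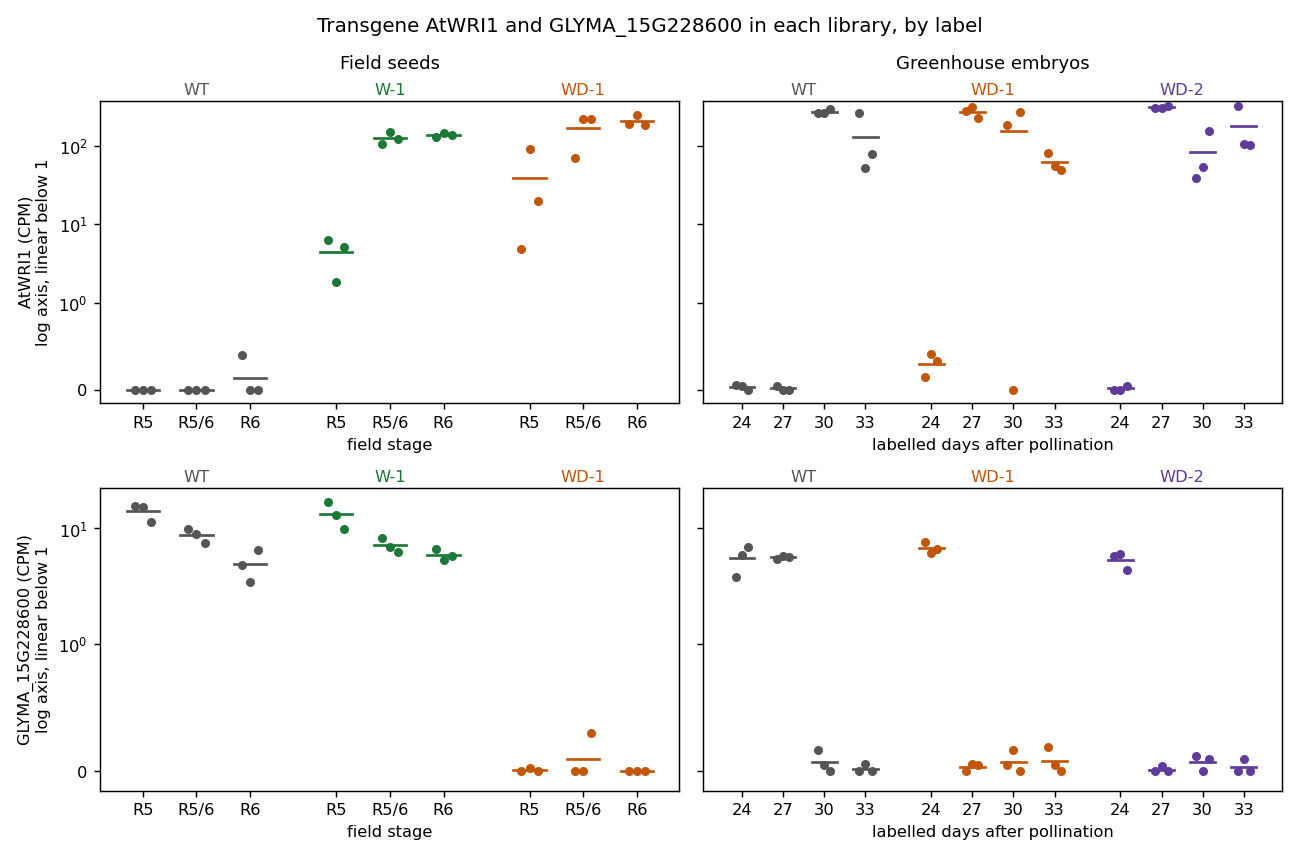
AtWRI1 (top) and GLYMA_15G228600 (bottom) in each library by labelled genotype and stage or day, in CPM on a log axis that is linear below 1; points are libraries and bars are means of 3. In the field AtWRI1 follows the labels, and GLYMA_15G228600 lies between 3.41 and 15.8 CPM in the WT libraries and at most at 0.303 CPM in WD-1.

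W-1 seeds differed from WT in 983 genes averaged over stages, 761 higher and 222 lower. The lower count rested on single libraries: it was 138, 123, 126 and 511 without W-1 R5 replicate 3, W-1 R5/6 replicate 1, W-1 R6 replicate 2 and WT R6 replicate 3. Without the last, 698 genes were higher. AtWRI1 had the largest rise. Among genes past the threshold with a mean of at least 5 CPM in the higher genotype and 1 direction of the fitted fold change at every stage, the largest rises of soybean genes were those of GLYMA_12G048800 and GLYMA_03G167400, which were near 0 in WT at every stage. At R6 they reached 28.1 ± 15.9 and 12.7 ± 5.20 TMM-normalized CPM in W-1, against 0.196 ± 0.294 and 0.0543 ± 0.0941 in WT. Their log2 fold changes over stages were 4.15 (SE 0.64, adjusted p = 0.000202) and 3.91 (SE 0.55, adjusted p = 6.48e-05), and 3.52 and 5.47 without WT R6 replicate 3. At R5 the fitted change of GLYMA_12G048800 was 0.35 (adjusted p = 1), while its means were 0.230 in W-1 and 0.239 in WT. GLYMA_14G136300 was lower in W-1 at every stage, at 0.367 ± 0.0634, 0.728 ± 0.646 and 0.923 ± 0.804 against 19.4 ± 4.59, 26.2 ± 1.81 and 23.2 ± 2.58 in WT (log2 fold change -4.80, SE 0.27, adjusted p = 1.46e-11). It was also lower in WD-1 at R5/6, at 7.01 ± 3.52 (log2 fold change -1.81, adjusted p = 0.00852), and did not pass the threshold there at R5 (-0.56, adjusted p = 0.779) or R6 (-1.08, adjusted p = 0.147). Averaged over stages its fall in WD-1 passed the threshold in all 27 alternatives. The log2 fold change was -1.42 to -1.07 with 1 library left out at a time. GLYMA_20G146200 rose in WT at R6 to 482 ± 606, with libraries from 74.9 to 1178, and was at 15.7 ± 21.7 in W-1 (log2 fold change -4.78 at R6, adjusted p = 0.00922). W-1 had 0 counts of this gene at R5 and R5/6, and its call over stages (adjusted p = 0.0221) was lost without WT R5 replicate 1, W-1 R5 replicate 3 or W-1 R5/6 replicate 1 (adjusted p = 0.0922, 0.0568 and 0.108).

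WD-1 seeds differed from WT in 1185 genes averaged over stages, 832 higher and 353 lower. GLYMA_08G003100 was higher in WD-1 with a log2 fold change of 4.66 (SE 0.44, adjusted p = 1.68e-07), and at R6 it reached 57.7 ± 29.1 TMM-normalized CPM against 0.877 ± 0.588 in WT. GLYMA_11G124400 had 0 counts in WT at R5/6 and R6 and was at 19.0 ± 11.3 in WD-1 and 21.6 ± 12.1 in W-1 at R6. Its call over stages in WD-1 (adjusted p = 0.0382) was lost without any of 7 libraries (WT R5 replicates 2 and 3, WD-1 R5 replicates 1 and 3, WT R5/6 replicate 3, WD-1 R5/6 replicate 2 and WT R6 replicate 3, adjusted p = 0.0551, 0.0522, 0.253, 0.1, 0.0521, 0.135 and 0.118). It was also lost with 2 unusual libraries left out (0.0503). GLYMA_15G007300 rose in WT to 61.5 ± 30.3 at R6 and was at 6.45 ± 1.95 in WD-1 (log2 fold change -3.18, adjusted p = 0.0069). Without WT R6 replicate 3 the WD-1 count over stages was 702, with 566 higher and 136 lower. The lower count was 221 without WT R5/6 replicate 3.

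GLYMA_15G228600 was nearly absent from WD-1. Its 9 WD-1 field libraries held 2 reads among 151.7 M, against 2318 among 216.5 M in WT and 1383 among 158.3 M in W-1. With reads pooled over libraries the WT level was 812 times that of WD-1 (95% counting interval 225 to 6704), with an adjusted p of 3.77e-14 for the edgeR test. As a ratio of mean CPM (9.26 ± 4.31 and 0.04 ± 0.10, n = 9 each) it was 246. The pooled ratio rests on 2 reads, and was 1316 without WD-1 R5 replicate 2 and 1589 without WD-1 R5/6 replicate 3, which hold 1 read each. The gene with the next identifier, GLYMA_15G228700, chosen after its values were seen, had 0 reads in WD-1 and 700 in WT. It was at least 163-fold lower against a floor of 3 counts over the 9 libraries. In W-1 neither gene differed from WT past the threshold (log2 fold changes -0.02, SE 0.17, adjusted p = 1, and 0.25, SE 0.23, adjusted p = 0.718).

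Of the 832 genes higher in WD-1, 83 lay in 1 stretch of 145 consecutive identifiers, GLYMA_13G203300 to GLYMA_13G217700, found after the results were seen. The 121 genes tested in it had a median log2 fold change of 1.03 (quartiles 0.73 and 1.24), with 118 above 0 and 0 lower past the threshold. The median was 1.00 at R5, 0.99 at R5/6 and 0.90 at R6. In W-1 the same genes had a median of 0.00, and the 100 genes beside the stretch had a median of -0.01 in WD-1. The limits of the stretch were set on the WD-1 field values. Its high median and the low median beside it therefore follow in part from that choice. Of the 1185 genes that differed between WD-1 and WT, 1102 lay outside the stretch, and 1043 of these passed when p-values were adjusted without its genes.

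The numbers of genes that differed from WT were larger at R6 than at R5 in both lines. W-1 differed in 15 genes at R5, 48 at R5/6 and 1728 at R6, where 1249 were higher and 479 lower. WD-1 differed in 69 genes at R5, 662 at R5/6 and 1260 at R6, where 913 were higher and 347 lower. GLYMA_01G081900, chosen after its values were seen, fell in WT from 17.8 ± 2.68 TMM-normalized CPM at R5 to 2.01 ± 0.755 at R6. In W-1 it went from 24.5 ± 2.61 to 131 ± 9.97 and in WD-1 from 24.8 ± 5.99 to 114 ± 9.10. The effect of the line on this gene was larger at R6 than at R5 by 6.03 on the log2 scale in W-1 (adjusted p = 6.31e-08) and by 5.79 in WD-1 (adjusted p = 1.49e-07). Such a difference between R6 and R5 passed the threshold for 659 genes in W-1 and 473 in WD-1. The W-1 count was 407 and 355 without W-1 R5 replicate 2 and W-1 R6 replicate 2. The WD-1 count was 307, 186 and 280 without WT R5 replicate 1, WT R6 replicate 3 and WD-1 R6 replicate 2, and 236 with only the libraries compared.

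Counts at R5 and R5/6 rested on few libraries. They also depended on the model. At R5, W-1 differed in 29 genes by DESeq2, 48 with no filter on low counts and 28 with 2 unusual libraries left out. WD-1 differed there in 130 by DESeq2, 8 with only the libraries compared, 9 with libraries over 10 M counts alone and 38 with the 2 libraries left out. At R5/6, W-1 differed in 122 genes by DESeq2, 17 with only the libraries compared, 25 with depth class as a covariate and 74 with the 2 libraries left out. Libraries over 10 M counts alone left only replicate 1 of W-1 there, so no count is given here. WD-1 differed at R5/6 in 1235 with libraries over 10 M counts alone and 173 with the 2 libraries left out. At R6 WD-1 differed in 497 (396 higher, 101 lower) with only the libraries compared. W-1 then had 999 higher and 281 lower, and 880 lower by DESeq2. The R5 count of W-1 was 9 without WT replicate 1 and 57, 101 and 8 without W-1 replicates 1, 2 and 3. That of WD-1 was 12, 232 and 14 without WT replicates 1, 2 and 3, 33 and 34 without WD-1 replicates 2 and 3, and 25 when adjusted without the GLYMA_13G stretch, outside which 37 of the 69 genes lay. At R5/6 the W-1 count was 20, 19 and 20 without WT replicates 1, 2 and 3 and 21 without W-1 replicate 2. The WD-1 count there was 322, 393 and 88 without those WT libraries and 145 and 220 without WD-1 replicates 1 and 2. WD-1 R5/6 replicate 1 lay at 41.8 on the first principal component (56.9% of variance), where WT R5/6 libraries lay between -31.5 and 2.9 and WT R5 libraries between 79.4 and 90.4. At R6 the W-1 count was 916 without W-1 replicate 2 (777 higher, 139 lower), and 812 genes were higher without WT replicate 1. The WD-1 count there was 466 without WT replicate 3 (423 higher, 43 lower) and 608 without WD-1 replicate 2 (471 higher, 137 lower). Libraries over 10 M counts alone left only WT replicate 3 and WD-1 replicate 2 of these groups at R6, so no R6 counts are given.

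**Figure D2:**
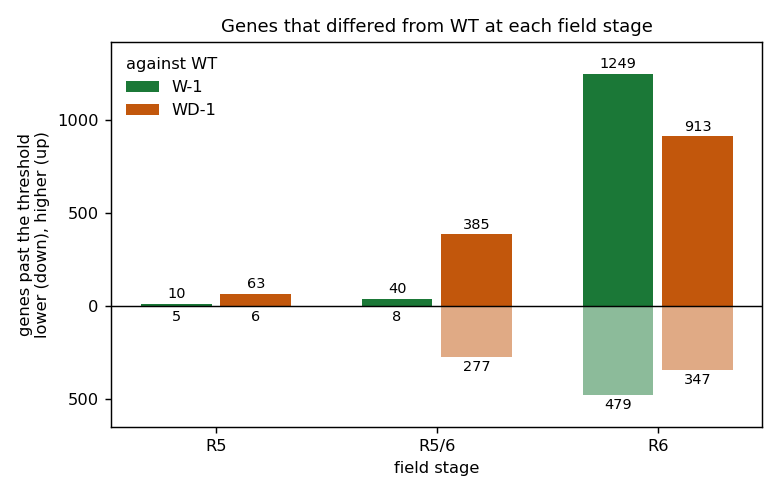
Genes that differed from WT at each field stage by the edgeR test, with higher genes as bars above 0 and lower genes as bars below 0, for W-1 and WD-1. W-1 has 1249 higher and 479 lower genes at R6, against 10 and 5 at R5.

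**Figure D3:**
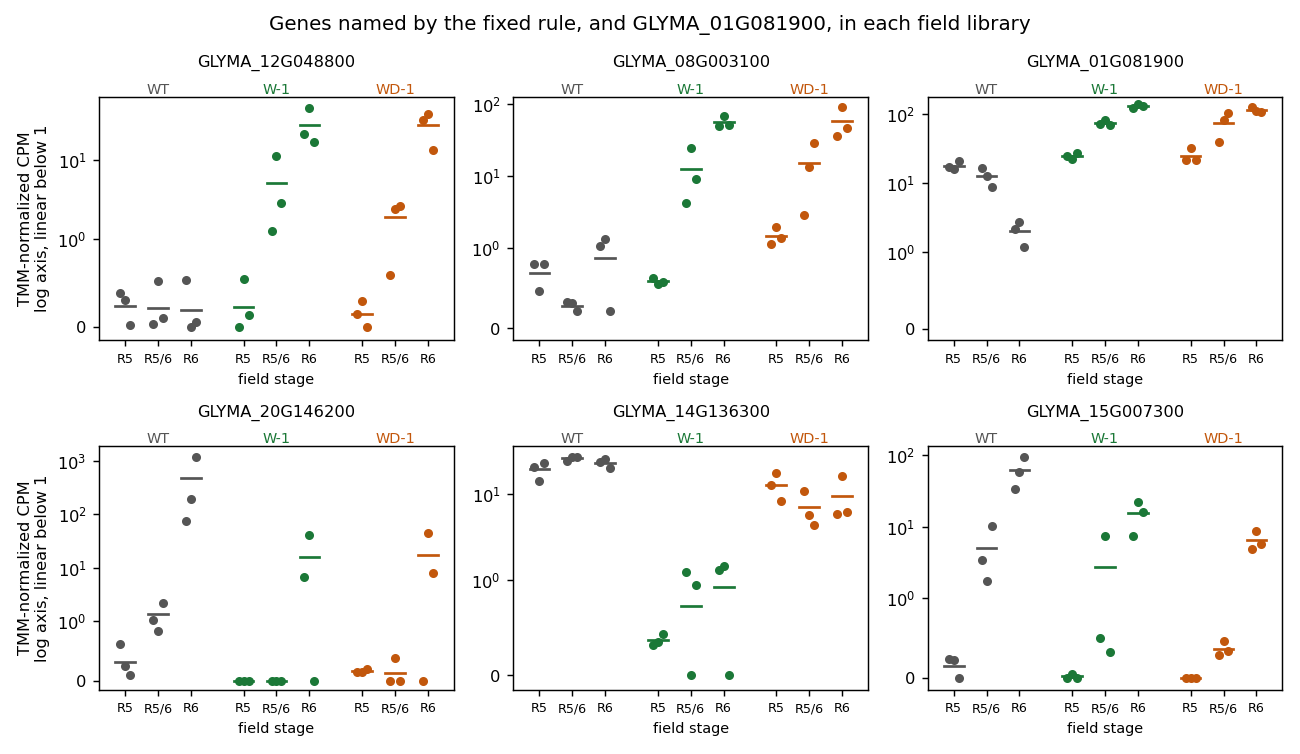
TMM-normalized CPM of 6 genes in each field library, on a log axis that is linear below 1; points are libraries and bars are means of 3. GLYMA_12G048800, GLYMA_08G003100 and GLYMA_01G081900 (chosen after its values were seen) are higher at R6 in W-1 and WD-1 than in WT.

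The genes that rose in W-1 and in WD-1 were largely shared. Without the transgenes, 760 genes were higher in W-1 and 830 in WD-1, and 501 were higher in both, where independent lists would share 16.2. Lower in both were 60 of 222 and 353 genes, where independent lists would share 2.01, and 2 genes went opposite ways. GLYMA_08G003100 was among the shared genes, at 56.1 ± 9.84 TMM-normalized CPM in W-1 and 57.7 ± 29.1 in WD-1 at R6. Both lines were set against the same WT libraries, and 8 simulations without any effect called 0 higher genes in either line, so their overlap of 0 says nothing about the overlap that shared controls create. The log2 fold changes across genes, which are not independent replicates, had a Pearson r of 0.516 against 0.498 in the simulations and a covariance of 0.204 against 0.0891, a difference of 0.115. With each line set against different WT libraries, 69, 70 and 123 genes were higher in both, out of 81, 89 and 192 higher in W-1 and 647, 652 and 433 in WD-1, where independent lists would share 1.33, 1.47 and 2.10. Lower in both were 2, 2 and 7 genes, out of 29, 27 and 37 in W-1 and 284, 227 and 85 in WD-1. Here W-1 was set against 1 WT library per stage, so its lists were shorter. With all WT libraries shared, part of the excess of 501 over 16.2 may come from the shared controls.

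WD-1 and W-1 seeds differed from each other in 216 genes averaged over stages, 171 higher and 45 lower in WD-1. GLYMA_12G111600 was at 4.23 ± 0.615, 5.57 ± 2.14 and 6.47 ± 1.61 TMM-normalized CPM in WD-1 at R5, R5/6 and R6, and at 0.770 ± 0.499, 0 and 0.403 ± 0.415 in W-1 (adjusted p = 1.79e-06). GLYMA_15G240300 was lower in W-1 than in both others, at 0.262 ± 0.323 at R6 against 5.56 ± 2.31 in WD-1 and 4.19 ± 1.38 in WT, with a log2 fold change of 4.47 between WD-1 and W-1 (SE 0.31, adjusted p = 6.33e-10). GLYMA_14G216100 was higher in W-1 at R6, at 10.7 ± 1.23 against 0.0186 ± 0.0322 in WD-1 and 0.429 ± 0.565 in WT (log2 fold change between the lines over stages -5.36, SE 0.42, adjusted p = 6.75e-09; -6.40 without WD-1 R6 replicate 2). GLYMA_15G228600 was the gene with the largest fall. The GLYMA_13G stretch held 73 of the 171 higher genes (42.7%), and 143 of the 216 genes lay outside it, of which 96 passed when p-values were adjusted without its genes. The lower count was 26 to 28 without W-1 R5 replicate 3, WD-1 R5 replicate 1, W-1 R5/6 replicate 1, WD-1 R5/6 replicates 1 and 2 or W-1 R6 replicate 2, and the higher count was 268 without WD-1 R6 replicate 2. The total was 140 without W-1 R5/6 replicate 1 (112 higher, 28 lower). Libraries over 10 M counts alone left only replicate 1 of W-1 at R5/6 and replicate 2 of WD-1 at R6, so no count is given here. By DESeq2 70 genes were lower, and 28 with 2 unusual libraries left out.

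Seed filling in WT changed 12,827 genes between R5 and R6, 5835 higher and 6992 lower at R6. GLYMA_01G081900 and GLYMA_15G007300 moved in opposite directions, the latter from 0.151 ± 0.131 to 61.5 ± 30.3 TMM-normalized CPM. Stage also led the first principal component of the field libraries, with R5 groups at 73.1 to 85.8 on average and R6 groups at -80.1 to -74.2. Without WT R6 replicate 3, 7354 genes differed between the stages.

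In the greenhouse the transgenes went against the labels in 13 of 36 libraries, so groups there are written as labelled. AtWRI1 was at 0.296 ± 0.134 CPM in the libraries labelled WD-1 and at 0.0172 ± 0.0298 in those labelled WD-2 at 24 DAP. It was at 271 ± 15.6 and 130 ± 113 in the libraries labelled WT at 30 and 33 DAP. At 27 DAP it was at 0.0175 ± 0.0304 in the libraries labelled WT, 269 ± 45.0 in those labelled WD-1 and 308 ± 10.5 in those labelled WD-2. AtDGAT had the same distribution, with 45.6 ± 8.81 CPM in the libraries labelled WT at 30 DAP and 0 in those labelled WT at 27 DAP. The library labelled WD-1 30 DAP replicate 2 held 0 counts of both transgenes in 5.82 M. GLYMA_15G228600 was at 5.60 ± 0.13 CPM in the libraries labelled WT at 27 DAP, and at 0.04 ± 0.03 in those labelled WD-1 and 0.01 ± 0.02 in those labelled WD-2. Its group means were 5.37 to 6.80 CPM for all 3 labels at 24 DAP and 0.02 to 0.08 CPM for all 3 at 30 and 33 DAP.

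Between libraries labelled by genotype at 27 DAP, where the transgenes followed the labels, 13,952 genes differed between WD-1 and WT (6957 higher, 6995 lower) and 8382 between WD-2 and WT (4640 higher, 3742 lower). At that time GLYMA_01G081900 was at 32.9 ± 0.817 TMM-normalized CPM in the libraries labelled WD-1 and 39.1 ± 1.42 in those labelled WD-2, against 0.0930 ± 0.0196 in those labelled WT. The order of the lines depends on the scaling, since CPM of all counts were 60.9 ± 4.04 in those labelled WD-1 and 47.6 ± 1.65 in those labelled WD-2. The transgenes speak to the genotype of these libraries and not to their day, so the counts may include a difference in day. On the first principal component (45.2% of variance) the libraries labelled WT, WD-1 and WD-2 at 27 DAP lay at 51.6 to 62.2, -10.8 to -6.2 and 12.6 to 14.8. The balance for WD-1 there turned to 7354 higher and 6485 lower with DESeq2 size factors, and 7728 and 6074 without the 16 abundant genes named below. With the 13 libraries left out of the model, the counts at 27 DAP were 15,279 and 9399.

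At the other times the directions rest on labels that the transgenes contradict. At 24 DAP, 4258 genes differed between libraries labelled WD-1 and WT and 8673 between those labelled WD-2 and WT, although none of the 9 libraries carried AtWRI1 above 0.408 CPM. At 30 DAP the counts were 3624 and 6113, where libraries of all 3 labels carried it. At 33 DAP edgeR called 0 genes in either comparison, with 1810 and 3964 genes at an unadjusted p under 0.05, and DESeq2 called 1 and 68. Without a filter on low counts edgeR called 48 genes in the libraries labelled WD-2 at 33 DAP, and with only the libraries compared 3. The 24 DAP count of WD-1 was 2694 without WT replicate 2 and 2414 without WD-1 replicate 2. The 30 DAP count of WD-1 was 348 (207 higher, 141 lower) with only the libraries compared and 2152 with libraries over 10 M counts alone. It was 2378 and 2212 without WT replicates 1 and 2 and 1933 and 2030 without WD-1 replicates 1 and 2. That of WD-2 was 3721 without WT replicate 3 and 3247 and 3139 without WD-2 replicates 1 and 2.

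Averaged over times, libraries labelled WD-1 differed from those labelled WT in 1167 genes (621 higher, 546 lower) and those labelled WD-2 in 1279 (867 higher, 412 lower). These averages take in the times at which the transgenes go against the labels. Other splits of the same libraries called up to 3409 and 7120 genes. The values below therefore describe labels and are not read as effects of genotype. AtWRI1 was higher in the libraries labelled WD-1 by a log2 fold change of 3.61 (SE 0.85, adjusted p = 0.0147; 0.0951 without WD-1 24 DAP replicate 2). AtDGAT had 3.47 there (SE 1.43, adjusted p = 0.179), and passed without WD-1 30 DAP replicate 2 (adjusted p = 0.00204), with libraries over 10 M counts alone (0.0072) and by DESeq2 (2.2e-06). In the libraries labelled WD-2 the values were 3.24 for AtWRI1 (SE 2.35, adjusted p = 0.527) and 3.61 for AtDGAT (SE 2.21, adjusted p = 0.434). Both passed there by DESeq2 (adjusted p = 7.93e-05 and 1.56e-06) and with only the libraries compared (0.0191 and 0.0086), and AtWRI1 with libraries over 10 M counts alone (0.0409). GLYMA_01G081900 was higher by 1.23 (SE 0.16, adjusted p = 2.67e-05) in the libraries labelled WD-1 and by 1.57 (SE 0.16, adjusted p = 1.81e-07) in those labelled WD-2. Its direction differed between times. It was higher under both labels at 27 DAP. At 24 DAP it was lower, at 0.310 ± 0.181 (WD-1) and 0.330 ± 0.133 (WD-2) TMM-normalized CPM against 2.345 ± 0.0937 (WT). At 30 DAP it was lower in those labelled WD-1 (22.9 ± 8.40 against 40.6 ± 3.66) and higher in those labelled WD-2. At 33 DAP the WD-1 and WD-2 means (49.7 and 50.1) lay within the spread of WT (47.7 ± 12.6). The soybean genes taken by the rule fixed in advance moved by 1.04 or less on the log2 scale. In the libraries labelled WD-1, GLYMA_13G200400 and GLYMA_10G253000 were higher by log2 fold changes of 0.63 (SE 0.13, adjusted p = 0.00652) and 0.62 (SE 0.11, adjusted p = 0.00255), and GLYMA_15G234000 and GLYMA_13G176300 had values of -0.90 (SE 0.15, adjusted p = 0.00131) and -0.71 (SE 0.13, adjusted p = 0.00222). In those labelled WD-2, GLYMA_09G172500 and GLYMA_15G023400 were higher by 0.75 (SE 0.13, adjusted p = 0.00045) and 0.73 (SE 0.09, adjusted p = 4.97e-06), and GLYMA_16G071500 and GLYMA_13G202100 had values of -1.04 (SE 0.19, adjusted p = 0.000837) and -0.93 (SE 0.16, adjusted p = 0.000358). Libraries labelled WD-2 and WD-1 differed in 4387 genes (2459 higher, 1928 lower), a balance that rests on the scaling: 2089 were higher and 2143 lower with DESeq2 size factors, and 1651 and 2386 without the 16 abundant genes. GLYMA_12G013100 was higher in those labelled WD-2 by 0.93 (SE 0.12, adjusted p = 1.03e-05) and GLYMA_06G028100 by 0.76 (SE 0.25, adjusted p = 0.0378), while GLYMA_16G189700 and GLYMA_11G025100 had values of -0.97 (SE 0.14, adjusted p = 8.27e-05) and -0.96 (SE 0.11, adjusted p = 2.5e-06). The call of GLYMA_06G028100 was lost in 14 of 31 alternatives (adjusted p up to 0.114).

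The lower count of WD-2 against WT as labelled was 264, 259, 271 and 235 without WT 24 DAP replicate 2, WT 30 DAP replicate 2, WT 33 DAP replicate 1 and WD-2 33 DAP replicate 2. It was 246 with libraries over 10 M counts alone (714 higher) and 622 by DESeq2 (1057 higher). The count of 1167 for WD-1 was 519 with libraries over 10 M counts alone, and rested on single libraries. Its balance turned to 544 higher and 646 lower without WT 30 DAP replicate 1, 1088 and 1356 without WD-1 30 DAP replicate 3 and 562 and 574 without WT 33 DAP replicate 1. It was 2444 without WD-1 30 DAP replicate 3, and 768 and 703 without replicates 1 and 2 of that group. Without WT 24 DAP replicate 2 or WD-1 24 DAP replicate 1 it was 764 and 666, and without WT 27 DAP replicate 3 or WD-1 27 DAP replicate 1 it was 777 and 740. Without WT 33 DAP replicate 3 or WD-1 33 DAP replicate 3 it was 604 and 762. Its lower genes alone, 546, were 357, 352, 340, 320, 351 and 359 without WT 24 DAP replicate 1 or 3, WD-1 24 DAP replicate 3, WT 30 DAP replicate 2 and WD-1 33 DAP replicate 1 or 2. Libraries labelled WT differed in 8117 genes between 33 and 24 DAP (4415 higher, 3702 lower at 33 DAP), a comparison of libraries with the transgenes to libraries without them. That count was 5238 and 5130 without WT 33 DAP replicates 2 and 3.

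A set of 16 genes led by GLYMA_13G021200, chosen after its values were seen, took a large share of the counts at later labelled times. Its share was 71.7 ± 14.5% in the libraries labelled WD-2 at 30 DAP, and 57.3 ± 30.5%, 76.8 ± 5.43% and 43.7 ± 31.4% in those labelled WT, WD-1 and WD-2 at 33 DAP. In the other greenhouse groups its mean share was 4.57 to 17.8%, and in the field groups 7.75 to 23.0%.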

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

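The tests of carried-over reads, of silent transgenes and of the near absence of GLYMA_15G228600 were chosen only after the results were seen; the test of the greenhouse labels and the splits of libraries were not.

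The effect of both transgenic lines differed between R6 and R5 by a test of the difference itself. In W-1 it did so for 659 genes, among them GLYMA_12G048800, with a log2 difference of 7.77 (adjusted p = 0.016), and GLYMA_01G081900, with 6.03. In WD-1 it did so for 473 genes, among them GLYMA_08G003100, with 6.23 (adjusted p = 0.0046), and GLYMA_01G081900, with 5.79. All 3 W-1 and all 3 WD-1 libraries at R6 lay above all WT libraries at R6 for these genes. The W-1 count was 407 without W-1 R5 replicate 2 and 355 without W-1 R6 replicate 2. The WD-1 count was 307, 186 and 280 without WT R5 replicate 1, WT R6 replicate 3 and WD-1 R6 replicate 2.

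In the greenhouse, AtWRI1 and AtDGAT were nearly absent from 6 libraries labelled WD-1 or WD-2 at 24 DAP and abundant in 6 labelled WT at 30 and 33 DAP. A candidate explanation is that labels and tables were joined in another order: genotype and time as labelled took 43.9% of the variance, and genotype and time as written in the names of the deposited tables took 67.2%, 23.3 percentage points more. Of 1000 random assignments 216 took at least as much as the labels (median 36.0%) and 0 as much as the names (highest 60.9%), and the presence of AtWRI1 over 10 CPM went against the genotype in the label in 13 of 36 libraries and against that in the name in 1. Carry-over of reads is argued against by the median AtWRI1 level in those 6 WT libraries, 86.3% of that in the libraries labelled WD-1 or WD-2 at 27 DAP, and silent transgenes would leave those in libraries labelled WT unexplained. Silent transgenes in the libraries labelled WD-1 at 24 DAP are argued against by GLYMA_15G228600, at 6.18 to 7.58 CPM there. In the 9 WD-1 field libraries it was at most at 0.303 CPM. Field R5 replicate 1 of WD-1 had 0 reads of it, with AtWRI1 at only 4.8 CPM and AtDGAT at 0.2. Those labelled WD-2 at 24 DAP held it at 4.34 to 6.02 CPM, but the field had no WD-2 libraries to compare. It stays open which genotype and day each library has. The GLYMA_13G stretch was at most -0.05 in the libraries labelled WD-1 at 24 DAP and at 0.92 to 1.10 in WD-1 field seeds. It was also at -0.02 ± 0.03 in those labelled WD-1 at 30 DAP, of which 2 carry AtWRI1 (184.6 and 272.0 CPM). Taken as labelled, the stretch thus does not mark the line. The third library of that group held 0 AtWRI1 reads where the mean level of the other 2 would give 1328. It held 1 read of GLYMA_15G228600 (0.17 CPM), nearly absent as in the libraries with the transgenes. GLYMA_01G081900, at 25.96 CPM in that library, was at most at 3.91 CPM in the greenhouse libraries whose names give WT. Field WT libraries at R5 held it at 21.71 to 29.24 CPM. No other biological explanation was tested.

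GLYMA_15G228600 and GLYMA_15G228700 held 2 and 0 reads in the 9 WD-1 field libraries, against 2318 and 700 in WT and 1383 and 589 in W-1. Too few reads in the WD-1 libraries are argued against by 1 read of GLYMA_15G228600 in the 5 WD-1 libraries over 10 M counts, where the WT level would give 1279, and an effect of AtWRI1 in any line by the log2 fold change of -0.02 (SE 0.17) in W-1. Loss of a stretch that reaches expressed neighbouring genes is argued against by the 5 tested genes within 10 identifiers with at least 1 CPM in WT: the lowest, GLYMA_15G228500, was at 53.3% of WT in WD-1, GLYMA_15G228400 was at 7.40 CPM in both and GLYMA_15G229400 at 108.9%, while the 6 identifiers between GLYMA_15G228700 and GLYMA_15G229400 had no tested gene. Libraries labelled WD-2 at 27 DAP, which carry both transgenes, held GLYMA_15G228600 at 0.01 ± 0.02 CPM and GLYMA_15G228700 at 0. Their GLYMA_13G stretch was at -0.05 ± 0.04, where WD-1 field seeds were at 0.92 to 1.10. Since the greenhouse labels are in doubt, it stays open whether WD-2 shares the loss. An effect that grows with the AtDGAT level is argued against by WD-1 R5 replicates 1 and 3. They had 0 reads of GLYMA_15G228600 with AtDGAT at 0.2 and 1.11 CPM, where WT at R5 was at 11.29 to 15.79 CPM. A variant or an insertion in both lines, a smaller loss and an effect of AtDGAT at any level, which W-1 lacks, stay open and were not tested. A variant or an insertion in WD-1 alone stays open only if the greenhouse labels are wrong by more than their order.

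Other splits of the same libraries tested how often as many genes are called by chance. Each set of 24 splits was drawn from a larger number, so 1 of 24 is the smallest share it can give. In the field only the real split gave as many genes over stages as W-1 (983, highest other 879) and WD-1 (1185, highest other 36). The same held for WD-1 against W-1 (216, highest other 126). In the greenhouse it held for WD-2 against WD-1 (4387, highest other 495), under labels that the transgenes contradict. A share of 1 of 24 met the limit fixed in advance. It does not firmly exclude chance, and for W-1 another split came close. The limit was not met for the libraries labelled WD-1 (1167, highest other 3409, 2 of 24) and WD-2 (1279, highest other 7120, 3 of 24) against those labelled WT. Splits that call several times the real count point to a structure of the samples other than the labelled genotypes.

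For groups of 3 against 3 there are 10 splits, too few to exclude chance. The real and highest other counts in the field were 15 and 20 for W-1 and 69 and 131 for WD-1 at R5, 48 and 2 for W-1 and 662 and 2 for WD-1 at R5/6, 1728 and 148 for W-1 and 1260 and 180 for WD-1 at R6, and 12,827 and 1 for WT R6 against R5. Among libraries as labelled they were 4258 and 0 for WD-1 and 8673 and 1 for WD-2 at 24 DAP, and 13,952 and 0 for WD-1 and 8382 and 0 for WD-2 at 27 DAP. They were 3624 and 648 for WD-1 and 6113 and 0 for WD-2 at 30 DAP, 0 and 0 for WD-1 and 0 and 277 for WD-2 at 33 DAP, where all 10 splits gave as many, and 8117 and 160 for WT 33 against 24 DAP. Splits were not drawn for the differences between R6 and R5.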

How the results depend on the processing

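The alternatives of depth, depth class, abundant genes, labels, unusual libraries and the GLYMA_13G stretch were chosen only after the results were seen. Of 449 counts under an alternative, 371 stayed within 1.5 times the reported count and 78 did not. Of the 371, the higher genes alone moved further in 4 and the lower genes alone in 46. Of 1071 values of named genes, 1031 kept their direction and side of the threshold, 27 lost the call, 8 gained it and 5 changed sign. The sign changes were of GLYMA_15G228600 in W-1 against WT, at -0.064 to 0.114 (log2) with 1 library left out at a time, and as low as -0.117 over all alternatives, with no adjusted p under 0.814. Averaged over stages, GLYMA_15G228600 in WD-1, GLYMA_14G136300 and GLYMA_12G048800 in W-1 and GLYMA_08G003100 in both lines kept direction and call in all 27 alternatives. The causes of the changes below were not tested.

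With the DESeq2 Wald test, 29 genes differed in W-1 and 130 in WD-1 at R5, 122 in W-1 at R5/6, and 1 and 68 at 33 DAP in the libraries labelled WD-1 and WD-2. With no filter on low counts, 48 differed in W-1 at R5 and 48 in those labelled WD-2 at 33 DAP. With only the libraries compared, 8 differed in WD-1 at R5, 17 in W-1 at R5/6, 497 in WD-1 at R6, 236 in the WD-1 effect at R6 against R5, 348 in those labelled WD-1 at 30 DAP and 3 in those labelled WD-2 at 33 DAP. With libraries over 10 M counts only, 942 differed between WD-1 and W-1, 9 in WD-1 at R5, 365 in W-1 and 1235 in WD-1 at R5/6, 519 in those labelled WD-1 over times and 2152 at 30 DAP. In that setting the counts for WD-1 against W-1 and for W-1 at R5/6 rest on single libraries. Only replicate 1 of W-1 was left at R5/6, and the first count also rests on only replicate 2 of WD-1 at R6. These counts are therefore not read as effects of depth. With depth class as a covariate, 25 differed in W-1 at R5/6. With 2 unusual libraries left out (WD-1 R5 replicate 3 and WD-1 R5/6 replicate 1), 28 differed in W-1 and 38 in WD-1 at R5, and 74 and 173 at R5/6. Without the stretch of GLYMA_13G genes, 96 differed between WD-1 and W-1 and 25 in WD-1 at R5.

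Leaving out 1 library at a time gave 701 to 1209 genes for W-1, 702 to 1214 for WD-1 and 140 to 318 for WD-1 against W-1 over stages. It gave 8 to 101 for W-1 and 12 to 232 for WD-1 at R5, 19 to 44 and 88 to 635 at R5/6, and 916 to 1641 and 466 to 1355 at R6. For WT R6 against R5 it gave 7354 to 11,828, and for the effects at R6 against R5 355 to 616 in W-1 and 186 to 658 in WD-1. Among libraries as labelled it gave 604 to 2444 for WD-1, 882 to 1480 for WD-2 and 3114 to 5869 for WD-2 against WD-1. By day it gave 2414 to 3777 and 6346 to 7802 at 24 DAP, 11,308 to 12,731 and 6596 to 7167 at 27 DAP, 1933 to 5400 and 3139 to 6761 at 30 DAP, and 0 to 1 and 0 to 1 at 33 DAP, for WD-1 and WD-2 in turn. For WT 33 against 24 DAP it gave 5130 to 8506.

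Scaling moved the fold changes of all genes together by at most 0.08 in size (log2). It moved the balance of calls in the libraries labelled WD-2 at 30 DAP from 2353 higher and 3760 lower to 2861 and 2981 with DESeq2 size factors, and to 2813 and 2996 without the 16 abundant genes. Without those genes the libraries labelled WD-1 had 794 higher and 417 lower over times (621 and 546 with them), and WD-2 against WD-1 had 1651 and 2386 (2459 and 1928 with them). The Wald test gave 1283 higher and 880 lower in W-1 at R6, against 1249 and 479.

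No set of groups met the rule for pairing of same-numbered replicates. In 0 of 9 field and 0 of 12 greenhouse sets was every correlation of their deviations over 0.1, with values from -0.311 to 0.498 and from -0.481 to 0.623. This rule does not exclude pairing in part: mean correlations in the greenhouse ran from -0.251 (WT and WD-2 as labelled at 27 DAP) to 0.376 (the same labels at 33 DAP). The replicate block gave 949 genes for W-1, 1107 for WD-1 and 196 for WD-1 against W-1 in the field, and 1240, 1389 and 4584 in the greenhouse; it moved no count by over 1.5 times and changed no call of a named gene. The label check could be run at 27 DAP alone, since other times lost a whole group. The gene list tests planned, with their estimated correlations, and the settings for normalized values were not run. In the 10 field libraries under 10 M counts, a count of 0 leaves up to 2.56 CPM.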

Other observations

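The tests of the GLYMA_13G stretch by AtWRI1 and by activity that falls off with distance and the gene classes by development were chosen only after the results were seen; the tests of neighbouring genes and of a duplicated stretch were not.

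Genes that rise during seed filling in WT were not called higher in W-1 more often than other genes. With classes from 2 WT libraries per stage and W-1 set against the remaining WT library, 7 of 2839, 7 of 3294 and 8 of 2325 rising genes were higher in W-1 (0.25, 0.21 and 0.34%). Of genes in neither class 0.40, 0.28 and 0.56% were higher, and of genes that fall in WT 0.74, 0.53 and 1.54%. In WD-1 the shares were 0.07, 0.06 and 0.82% of rising, 0.28, 0.08 and 2.06% of falling and 0.11, 0.07 and 0.65% of other genes. Lower in W-1 were 0.04, 0.30 and 0.86% of rising, 0.72, 0.12 and 0.08% of falling and 0.10, 0.07 and 0.06% of other genes. Lower in WD-1 were 0.11, 0.15 and 1.76% of rising, 0.07, 0 and 0.16% of falling and 0.01, 0 and 0.12% of other genes. By camera no class moved past the threshold with an estimated correlation (adjusted p from 0.404 to 0.792), while the preset gave the rising class as lower in WD-1 in all 3 (adjusted p = 0.0206, 0.000298 and 0.00054) and in W-1 in 1 of 3 (adjusted p = 0.00103). The preset gave the falling class as higher against WT replicate 3 alone (adjusted p = 0.0306 in W-1 and 0.000889 in WD-1).

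Genes higher in WD-1 lay side by side in identifier order. WD-1 against WT had 88 neighbouring pairs of genes called in 1 direction, where shuffled orders gave 20.8 on average (permutation p = 0.0001, the smallest that 10,000 shuffles can give) and as many genes from the WT stage comparison gave 34. WD-1 against W-1 had 49 pairs (shuffled 0.8, permutation p = 0.0001, stage comparison 3). W-1 against WT had 18 (shuffled 16.0, permutation p = 0.345, stage comparison 27). The window of 50 tested genes with the most calls held 38 in WD-1 against WT, from GLYMA_13G207600 to GLYMA_13G213700, and 7 in W-1.

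The genes from GLYMA_13G203300 to GLYMA_13G217700 were close to 2-fold higher in WD-1 field seeds: the median over the stretch lay between 0.92 and 1.10 on the log2 scale in the 9 WD-1 libraries, between -0.05 and 0.11 in W-1 and between -0.07 and 0.15 in WT. AtWRI1 as the cause in any line is argued against by the median of 0.00 in W-1, and activity that falls off with distance from 1 insertion by the libraries labelled WD-1 at 27 DAP, which did not set the limits of the stretch: its 3 parts were at 0.85, 1.03 and 0.88, and the 10 genes just before and after it at -0.15 and -0.13. A duplicated stretch may account for an even rise. In the greenhouse the stretch was at 0.85 to 0.98 relative to the libraries labelled WT at 27 DAP under these labels: WD-1 at 27 DAP, WT and WD-2 at 30 DAP and all 3 at 33 DAP. These are more groups than WD-1 can fill, which has 4 of the 12 as labelled. If the labels were only reordered, a rise confined to WD-1 is argued against. In the libraries labelled WD-1 at 27 DAP the median was 0.88 above those labelled WT, but those labelled WD-1 at 30 DAP were at -0.02 relative to the same WT libraries, and since the greenhouse labels are in doubt this test leaves duplication open. An insertion that acts evenly up to sharp limits and a difference between the lines' parents or selection history were not tested.

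The same stretch divided the greenhouse groups as labelled. Relative to the libraries labelled WT at 27 DAP, its median was 0.93 ± 0.02, 0.90 ± 0.06, 0.85 ± 0.15, 0.97 ± 0.00 and 0.98 ± 0.05 in those labelled WT and WD-2 at 30 DAP and WT, WD-1 and WD-2 at 33 DAP. It was -0.09 ± 0.00, -0.06 ± 0.01 and 0.04 ± 0.04 in those labelled WT, WD-1 and WD-2 at 24 DAP, and -0.05 ± 0.04 in those labelled WD-2 at 27 DAP, which carried AtWRI1 at 308 ± 10.5 CPM.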
